A study of Mus musculus with 18 samples.

How the data were processed

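RNA was sequenced from kidney cortex of C57Bl/6 mice of 2 genotypes. Klf15fl/fl mice (fl/fl) carry floxed alleles of Klf15, a zinc finger transcription factor, and Klf15PTKO mice (PTKO) lack it in the proximal tubule. Mice of each genotype received vehicle (DMSO), aristolochic acid I, a plant toxin that damages the proximal tubule, for 2 weeks (AA 2wk), or the same course followed by 2 weeks of remodeling (AA 4wk). This gives 6 groups with 3 libraries each, 18 libraries in all. The kidneys were perfused with PBS, and the cortex was kept in RNAlater. RNA was extracted with RNeasy columns and DNase treatment, and libraries were made with a TruSeq Stranded Total RNA kit. The exons removed from Klf15 and the Cre line are not given in the sources used here. The labels name no group with Cre and intact Klf15. A genotype effect therefore cannot be told apart from an effect of the Cre transgene. Neither do the labels state that the 3 replicates of a group are separate mice, so the p-values measure only the spread between samples.

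The deposited values are RPKM (read density scaled by transcript length and library depth), per the file headers, for 24062 genes in 18 libraries. The submitters' processing notes name bcl2fastq 2.19, kallisto (version not given) and genome build mm10. How the reads were assigned to genes for the RPKM table and which annotation was used are not given in the sources used here. For 17578 of the 17579 genes with a value above 0 in at least 6 libraries, all but Gpx3, or 99.994% of these genes, the steps between values allowed whole read numbers to be recovered, with a tolerance of 0.02 reads for a value called whole. The recovered depth runs from 10.7 to 21.2 M reads per library, and 11323 to 13254 genes reach 1 RPKM in a library. In both AA 2wk groups the library numbered 3 is the shallowest (11.9 M reads in fl/fl and 11.5 M in PTKO). No pair of libraries holds identical values. Of the gene names, 27 read as dates. Mitochondrially encoded genes are not in the table.

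Genes with at least 1 RPKM in at least 3 of the 18 libraries were tested, 13624 in all, on log2(RPKM + 1). A single limma fit (limma 3.58.1, statmod 1.5.0, R 4.3.3) with the 6 group means, an intensity trend and robust empirical Bayes moderation gave 11 comparisons. These are the genotype effect within each treatment, the effect of each AA course within each genotype, AA 4wk against AA 2wk within each genotype, and the interaction of genotype with each AA course. The labels give no week for the DMSO libraries, and the same DMSO group of a genotype serves both courses. The effects of both courses are therefore not independent, and not both can be matched in time to their vehicle. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 13624 genes, with calls at 0.05. Log2 fold changes are given with their SE from that fit, and RPKM values as mean with SD over 3 libraries. An exact permutation test of 3 libraries against 3 cannot go below 0.1, which is why a fit across all genes was used.

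Before the data were examined, 36 gene lists were fixed, together with the comparisons, the threshold, the filter and the other settings to be tried. Metabolic lists hold fatty acid oxidation, peroxisomal lipid metabolism, PPAR-alpha targets, branched-chain amino acid breakdown, gluconeogenesis, glycolysis, oxidative phosphorylation, the TCA cycle and mitochondrially encoded genes. Response lists hold tubule injury, p53 targets, extracellular matrix, fibroblast, inflammation, cell cycle, NRF2, unfolded protein response, immediate early and heat shock, circadian, glucocorticoid-responsive and KLF family genes. The NRF2 list, called NRF2 targets for short, also holds genes of aristolochic acid metabolism and NRF2 itself. Cell type lists hold proximal tubule, macrophage, T cell, B and plasma cell, neutrophil, endothelial, podocyte, thick ascending limb, distal convoluted tubule, collecting duct principal, intercalated, adipocyte, adrenal and erythroid markers. A last list, called sex-biased for short, holds sex-linked and sex-biased kidney genes. It mixes genes of both sexes, such as Xist and Ddx3y, so its direction marks no shift toward one sex. Of these, 32 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists. Camera compares a list with all other tested genes. A list it calls higher or lower is so relative to them, and an uncalled list may still have moved with them. Camera with an estimated correlation and fry served as alternatives. Some genes stand in more than 1 list: Ppargc1a (PPAR-alpha and gluconeogenesis), Sdha and Sdhb (oxidative phosphorylation and TCA cycle), Thy1 (fibroblast and T cell), Per1 (circadian and glucocorticoid), Klf9 (glucocorticoid and KLF family) and Cdkn1c (glucocorticoid and podocyte). Many tubule markers are also expressed at some level along other segments of the cortex.

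Genes to be named were set by a rule fixed at the same time. Klf15 is given in every sample. In each comparison with calls, the 5 rising and 5 falling genes with the largest change are named if all 3 libraries of one group lie beyond those of the other and the higher group mean is at least 5 RPKM. For interactions the separation was not required, and unnamed gene models were counted but not named. Up to 4 called members per list follow, and 20 genes of injury, fat oxidation, transport, matrix and inflammation were candidates whether called or not. From these candidates, examples are given in the text, and some are not reported here. Adgre1 is listed under its former name Emr1. Positions are from the GENCODE annotation of mm10, where 221 of 224 named genes had a single position.

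The other settings fixed at that time were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 RPKM, median-of-ratios scaling, quantile normalization, sample quality weights, no trend or robust step, replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Added after the data were seen were voom on the recovered reads, leaving out both AA 2wk libraries numbered 3, and a replicate block within the AA 2wk groups. The numbers of the replicates were taken as a possible pairing where residuals of libraries with the same number correlated above 0.1 in each pair. This was met only in the genotype effect at AA 2wk, with 0.43 as the lowest correlation. Even there PTKO number 1 correlated more with an fl/fl library of another number.

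The procedure was tested on simulated data with known changes. At a 2-fold change it recovered 83.6% of changed genes in the DMSO genotype comparison, 88.1% at AA 2wk, 88.1% at AA 4wk, 94% for the AA 2wk effect and 71.6% in an interaction, with 7, 7, 2, 11 and 5 false calls. At 1.5-fold these shares were 55.2%, 53.7%, 47.8%, 55.2% and 23.9%, and at 4-fold 98.5%, 98.5%, 97%, 100% and 89.4%. A list shifted by -0.3 was called in each of the 5 settings, with 1 other list called in all. The simulated noise was independent between genes, so the list tests were not tested under correlated genes. For each gene it had the same spread in every group, and changes were planted only in genes with a mean log2(RPKM + 1) of at least 2. The real replicates correlated less at AA 2wk (as low as 0.944) than in DMSO (0.979 or more). The shares and false calls thus hold for the simulated setting and may differ in these data. The recovery of reads was tested on a simulated table and gave the true number, up to a common factor, for 100% of the genes that it converted. Computations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.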

Results

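Loss of the transcription factor Klf15 from the proximal tubule was studied in mouse kidney cortex at rest, after aristolochic acid I, and after a remodeling period, to ask how the tubule's metabolism and injury depend on Klf15. The toxin set the main axis of the data. The first principal component held 81.9% of the variance, with DMSO libraries from -90.0 to -66.1 and AA 4wk libraries from 37.7 to 65.9. Most AA 2wk libraries lay between 34.0 and 48.6. The library numbered 3 stood apart in both genotypes, at -7.3 in fl/fl and -7.1 in PTKO, between vehicle and toxin. In these 2 libraries the injury list stood 2.58 and 2.82 above the fl/fl DMSO mean, and the proximal tubule list stood at -0.84 and -0.89. The other AA 2wk libraries had injury means of 3.37 to 3.78 and tubule means of -1.82 to -1.44 (mean log2 difference). Correlation between replicates, across genes, ran from 0.979 to 0.995 in DMSO, 0.944 to 0.987 at AA 2wk and 0.986 to 0.992 at AA 4wk.

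**Figure D1:**
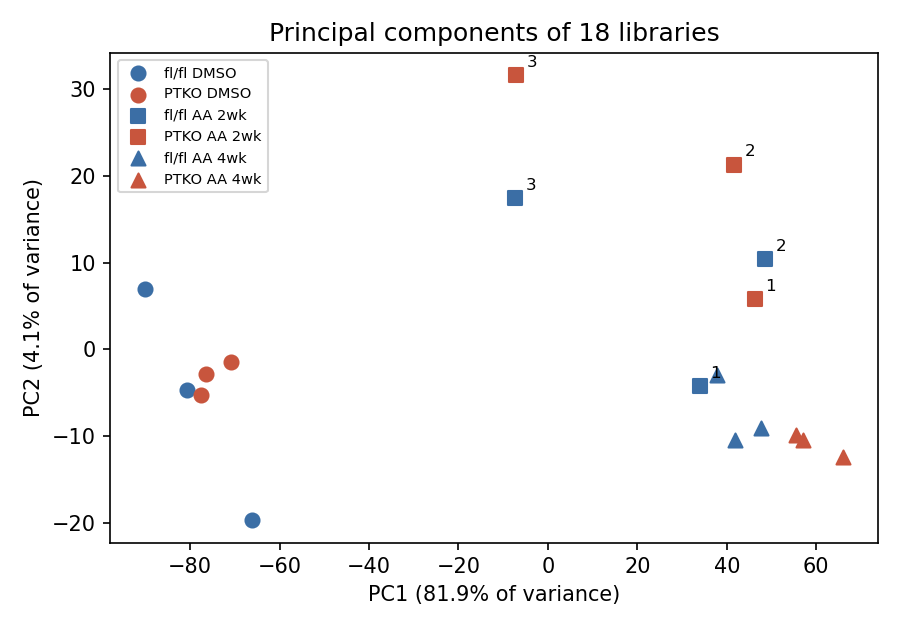
Principal components of log2(RPKM + 1) over the 13624 tested genes, one point per library, with the first component (81.9% of variance, x axis) against the second (4.1%, y axis), both without units. Blue points are fl/fl and red points PTKO, and the AA 2wk libraries carry their number: both numbered 3 lie at -7.3 and -7.1, away from the other AA libraries.

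Klf15 itself fell with the toxin. In fl/fl cortex its mean dropped from 59.9 ± 6.33 RPKM in DMSO to 27.6 ± 12.1 at AA 2wk and 15.0 ± 3.61 at AA 4wk (n = 3 each). The log2 fold changes were -1.17 ± 0.26 (adjusted p = 0.00136) and -1.95 ± 0.26 (adjusted p = 1.76e-05). In PTKO cortex the means were 31.0 ± 2.2, 18.5 ± 6.61 and 9.15 ± 0.361 RPKM, with changes of -0.76 ± 0.26 (adjusted p = 0.0193) and -1.65 ± 0.26 (adjusted p = 5.2e-05). Leaving out PTKO DMSO number 2 or 3 or PTKO AA 2wk number 1 or 2 took the adjusted p of the 2-week change in PTKO to 0.0505, 0.0537, 0.109 and 0.05. The interaction of genotype and toxin for Klf15 was 0.40 ± 0.36 at AA 2wk (adjusted p = 0.968) and 0.29 ± 0.36 at AA 4wk (adjusted p = 0.951).

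Between genotypes, every PTKO library in DMSO (28.4, 31.9 and 32.6 RPKM) lay below every fl/fl library (53, 61.3 and 65.5 RPKM), a separation that chance gives in 0.1 of such groupings. The fitted genotype effects of Klf15 were -0.93 ± 0.26 in DMSO, -0.52 ± 0.26 at AA 2wk and -0.63 ± 0.26 at AA 4wk, and limma called none of these over all genes (adjusted p = 0.595, 0.763 and 0.812). The effect at AA 2wk leans on fl/fl AA 2wk number 3, without which it was -0.2 (adjusted p = 0.808). In DMSO the effect passed with sample quality weights (adjusted p = 0.00322), without both AA 2wk libraries numbered 3 (0.029), with a replicate block within the AA 2wk groups (0.037) and in a fit of the DMSO groups alone (0.0341). Over all settings its adjusted p ran from 0.00322 to 1. Klf15 lies on chromosome 6, 90462576 to 90475238, plus strand, with up to 4 exons, and the table holds 1 value per gene, so removed and remaining exons cannot be told apart.

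**Figure D2:**
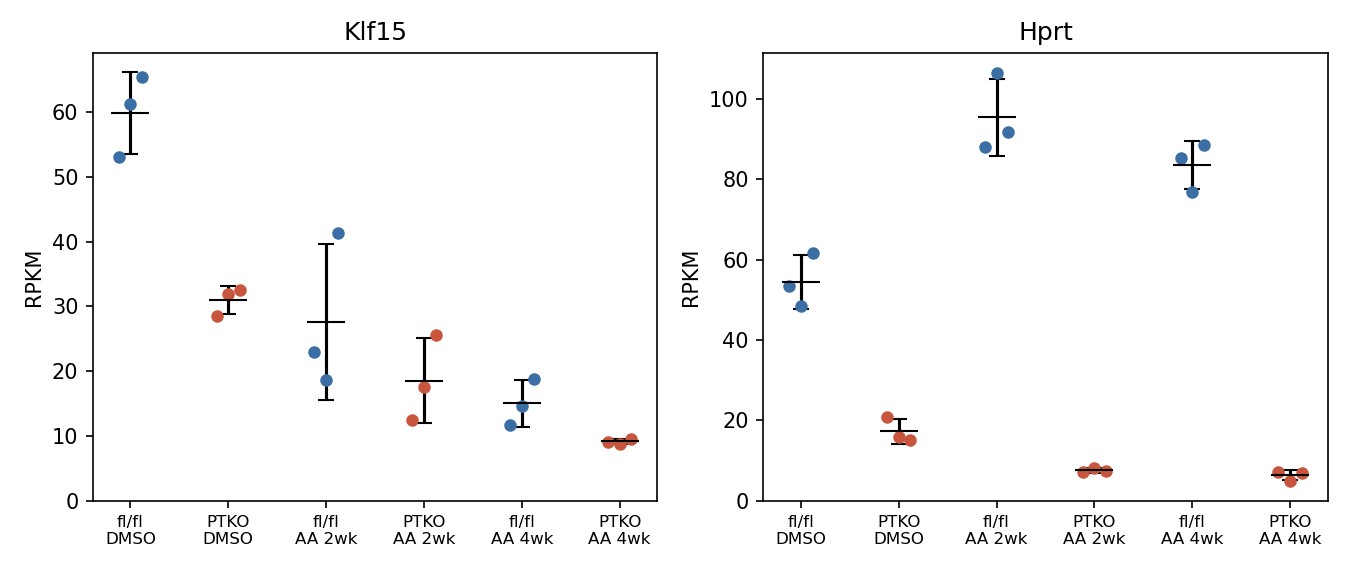
Klf15 and Hprt in RPKM (y axis, from 0) for each library by treatment (x axis), fl/fl in blue and PTKO in red, with points for libraries and bars for mean and SD of 3. Klf15 lies at 59.9 RPKM in fl/fl and 31.0 RPKM in PTKO cortex in DMSO, and Hprt at 17.3, 7.49 and 6.25 RPKM in the 3 PTKO groups.

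Without toxin, PTKO cortex differed from fl/fl cortex in 5 called genes, 2 higher and 3 lower. Hprt, the purine salvage enzyme, was lower by the largest amount, at 17.3 ± 3.12 against 54.5 ± 6.67 RPKM (n = 3 each, log2 fold change -1.61 ± 0.14, adjusted p = 9.52e-05). Gpc3, a cell surface proteoglycan, was higher at 22.3 ± 5.48 against 9.27 ± 1.18 RPKM (1.16 ± 0.18). So was Tmem86a (0.86 ± 0.14). Smarca2, a chromatin remodeling ATPase, and Fam102a were lower (-0.60 ± 0.09 and -0.46 ± 0.07), each of these 4 with an adjusted p of 0.0399. Hprt and Gpc3 both lie on the X chromosome (52988137 to 53021659, plus strand, and 52272426 to 52613950, minus strand), while Tmem86a is on 7, Smarca2 on 19 and Fam102a on 2.

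The genes of injury and fat oxidation were not called in DMSO. Havcr1, the kidney injury molecule, was 8.84 ± 13.9 RPKM in PTKO and 0.642 ± 0.224 in fl/fl cortex, with 24.9 RPKM in PTKO number 3 and 0.978 and 0.62 in the others (1.42 ± 0.86, adjusted p = 1.0). Lcn2, a lipocalin released by damaged tubules, gave 0.83 ± 0.57, and Cpt1a, the entry enzyme of mitochondrial fat oxidation, -0.18 ± 0.23. Acadm, a medium-chain dehydrogenase, gave 0.11 ± 0.19, all with adjusted p = 1.0. Without PTKO DMSO number 3 Havcr1 gave 0.13 and Lcn2 0.19, so both values rest largely on that library. At an unadjusted p under 0.05 there were 673 genes, where chance gives 681, and voom on recovered reads called 5, of which 3 are among the 5 named here. A fit of the DMSO groups alone called 11, of which 1 is among them, and quality weights gave 1177. The calls on Gpc3, Tmem86a, Smarca2 and Fam102a are at the edge of the threshold. Over the settings their adjusted p ran from 0.000138 to 0.225, 1.53e-05 to 0.299, 0.000115 to 0.412 and 0.000206 to 0.299, against 3.06e-06 to 0.0225 for Hprt. For Gpc3 the leave-outs of fl/fl DMSO number 1, 2 and 3 gave 0.225, 0.0591 and 0.122, and those of PTKO DMSO number 1, 2 and 3 gave 0.0603, 0.135 and 0.0861, while each AA 4wk library left out gave 0.0542 to 0.0807. The count of calls was 1 to 3 when a DMSO library was left out, 2 without fl/fl or PTKO AA 2wk number 1, 1 when an AA 4wk library was left out, 8 without fl/fl AA 2wk number 3, 10 without PTKO AA 2wk number 3 and 34 without both.

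As groups, 9 of the 32 lists were called between genotypes in DMSO, 3 higher and 6 lower, though none with an estimated correlation. The circadian list was lower with a median of -0.35, where 2 members were higher and 7 lower adjusted over the list alone and 0 over all genes (adjusted p = 5.54e-05, and adjusted p = 0.214 with an estimated correlation). The injury list was higher in 25 of 26 members, with a median of 0.35 (adjusted p = 5.54e-05, and 0.997 with an estimated correlation). Its mean over PTKO DMSO libraries stood 0.43 ± 0.35 above fl/fl DMSO (mean log2 difference, SD of 3). Without PTKO DMSO number 3 its members Havcr1 and Lcn2 gave only 0.13 and 0.19. Smaller shifts were seen in branched-chain amino acid breakdown (-0.16, adjusted p = 0.00229), extracellular matrix (0.34, 0.0309) and glucocorticoid-responsive genes (-0.12, 0.0309). The rest were fatty acid oxidation (-0.11, 0.037), PPAR-alpha targets (-0.16, 0.037), glycolysis (0.11, 0.037) and intercalated cells (-0.21, 0.037). With an estimated correlation the adjusted p was 0.527 for the glucocorticoid list and 0.997 for the other 6. Without fl/fl DMSO number 3 these 7 lists lost their calls (0.0999, 0.639, 0.251, 0.639, 0.124, 0.148 and 0.18 in the order given), and the other DMSO libraries ended all of them but branched-chain amino acid breakdown when left out, with adjusted p from 0.0519 to 0.29. Median-of-ratios scaling ended the last 5 calls as well, with 0.057, 0.13, 0.0744, 0.0517 and 0.0912.

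After 2 weeks of toxin, fl/fl cortex showed heavy tubule injury and a p53 response. Havcr1 rose from 0.642 ± 0.224 to 528 ± 82.6 RPKM (n = 3 each, log2 fold change 8.33 ± 0.86, adjusted p = 3.92e-06), and Lcn2 from 1.51 ± 0.851 to 332 ± 223 RPKM (6.80 ± 0.57, 7.68e-07). Cdkn1a, the cell cycle inhibitor and p53 target, rose from 3.05 ± 0.884 to 355 ± 30.4 RPKM (6.47 ± 0.18, adjusted p = 5.11e-12). Sprr1a, a barrier protein of squamous epithelia, and S100a6, a calcium-binding protein, rose by 6.71 ± 0.68 and 6.12 ± 0.52. All 26 genes of the injury list rose (median 3.08, adjusted p = 4.31e-08, and 0.445 with an estimated correlation), among them Krt20, a keratin (5.30 ± 0.54), and Vcam1, an adhesion molecule (3.47 ± 0.52). Of 24 p53 targets, 22 rose and 0 fell (mean over 3 libraries 2.38 ± 0.11, adjusted p = 2.52e-09, and 0.438 with an estimated correlation), with Phlda3 at 4.58 ± 0.26, Gdf15 at 4.36 ± 0.16 and Mdm2 at 2.74 ± 0.30. All 23 cell cycle genes rose as well (median 2.09, adjusted p = 8.58e-06, and 0.607 with an estimated correlation), such as Ube2c (3.18 ± 0.48), Top2a (2.99 ± 0.42) and Mki67 (2.46 ± 0.38).

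Proximal tubule and fuel metabolism genes fell. The organic anion carrier Slco1a1 went from 113 ± 66.3 to 0.786 ± 0.492 RPKM (-5.87 ± 0.31, adjusted p = 1.87e-08), and the androgen-regulated Kap from 44500 ± 5790 to 2807 ± 2030 RPKM (-4.22 ± 0.55, 2.64e-05). Inmt (-5.11 ± 0.48), Slc7a13 (-4.53 ± 0.49) and Pzp (-4.21 ± 0.23) fell as well. Of 26 proximal tubule markers, 18 fell and 0 rose (median -1.17, adjusted p = 1.05e-13, and 0.385 with an estimated correlation), including the uptake transporter Slc22a6 (-3.24 ± 0.57), the aminoacylase Acy3 (-3.15 ± 0.26), the phosphate transporter Slc34a1 (-1.31 ± 0.34) and megalin, Lrp2 (-1.92 ± 0.31). In fatty acid oxidation 18 of 25 genes fell and 0 rose (median -0.73, adjusted p = 2.78e-14), with Acadm going from 444 ± 12.5 to 153 ± 38.7 RPKM (-1.56 ± 0.19, 1.16e-05). Peroxisomal lipid metabolism lost 15 of 18 genes and gained 1 (median -0.89, 8.69e-12), with Amacr at -2.48 ± 0.20. Branched-chain amino acid breakdown lost 15 of 21 (median -0.74, 7.55e-13), with isovaleryl-CoA dehydrogenase, Ivd, at -1.65 ± 0.18. With an estimated correlation the adjusted p was 0.385 for each of these 3 lists.

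In the TCA cycle 13 of 17 genes fell (median -0.46, adjusted p = 9.92e-08), with Dlst at -0.63 ± 0.12, and in gluconeogenesis 6 of 8 fell and 1 rose (median -1.08, 0.00138), with G6pc at -2.25 ± 0.43. For both the adjusted p was 0.445 with an estimated correlation, and quantile normalization gave 0.071 and 0.0731. In oxidative phosphorylation 14 of 43 genes fell, 4 adjusted over the list alone, with Ndufs1 of complex I at -0.66 ± 0.15 (median -0.24, adjusted p = 1.48e-09, and 0.576 with an estimated correlation). Its call ended under quantile normalization, with a median of -0.01 (adjusted p = 0.899). Cpt1a fell by 0.55 (adjusted p = 0.0487), but without fl/fl AA 2wk number 2 the adjusted p was 0.275, without fl/fl DMSO number 1, 2 or 3 it was 0.0976, 0.0663 and 0.113, and 19 settings in all ended this call. The fatty acid sensor Ppara fell by 0.84 (0.0211), with 0.116 without AA 2wk number 2, 0.0996 without AA 2wk number 1 and 0.0527 without DMSO number 3, while Ppargc1a gave 0.05 ± 0.18 (0.814). PPAR-alpha targets split, with 4 of 17 risen and 6 fallen, a median of 0.05, a mean of -0.10 and an uncalled test in the lower direction (0.0657). Here the lipid droplet gene Plin2 rose by 1.47 ± 0.13 and Cyp4a10 fell by 1.71. Glycolysis was not called (median 0.49, adjusted p = 0.454), although 9 of 16 genes rose and 1 fell, with the glucose carrier Slc2a1 at 1.5 ± 0.12.

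Matrix and immune genes rose. Collagen gene Col1a1 rose by 2.95 ± 0.86 (adjusted p = 0.00813), Fn1 by 2.71 ± 0.53 (0.000581) and Tgfb1 by 2.11 ± 0.27 (1.95e-05), and 25 of 29 matrix genes rose, 26 adjusted over the list alone (median 1.87, adjusted p = 0.00391, and 0.762 with an estimated correlation). Complement C3 rose by 4.99 ± 0.53 and the chemokine Ccl2 by 4.24 ± 0.71, with 19 of 21 inflammation genes risen, 21 over the list alone (median 2.50, adjusted p = 2.22e-05, and 0.576 with an estimated correlation). All 13 macrophage markers rose (median 3.11, adjusted p = 0.000254, and 0.576 with an estimated correlation), with lysozyme, Lyz2, at 5.50 ± 0.72 and Adgre1 (Emr1) at 2.66 ± 0.51. All 10 T cell markers rose (median 2.44, adjusted p = 0.0335, and 0.755 with an estimated correlation), with Cd3g at 3.03 ± 0.60. This T cell call ended without fl/fl DMSO number 2 (0.0856) or AA 2wk number 1 (0.0593) or 2 (0.0656), and with voom (0.194). Among libraries, macrophage genes stood 3.12 ± 1.07 above the fl/fl DMSO mean and matrix genes 2.11 ± 0.77 (mean log2 difference, SD of 3), a spread that includes the low library numbered 3.

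Among the remaining lists, the sex-biased genes were lower, with 6 of 11 fallen and 2 risen (median -1.27, adjusted p = 0.000288, and 0.257 with an estimated correlation), such as Cyp2e1 at -3.27 ± 0.52. The circadian list was called lower relative to all other genes, with 4 of 15 risen and 3 fallen (median -0.13, adjusted p = 0.0464, and 0.445 with an estimated correlation). Both scalings ended that call (0.24 and 0.221), as did leaving out fl/fl DMSO number 1 (0.0505) or 2 (0.0793), AA 2wk number 1 (0.0656) or 2 (0.101) or AA 4wk number 2 (0.0506). The KLF family was not called (10 of 14 risen, 2 fallen, median 0.82, adjusted p = 0.363), with Klf5 at 2.88 ± 0.32 and Klf6 at 2.59 ± 0.29. Neither were immediate early and heat shock genes (9 of 12 risen, 1 fallen, 1.21, 0.235), nor the unfolded protein response (8 of 11 risen, 0.83, 0.227), with Atf3 at 2.64 ± 0.35, nor glucocorticoid-responsive genes (4 of 10 risen, 0.55, 0.692). Fibroblast markers (9 of 11 risen, 1.18, 0.314), B and plasma cells (1 of 4 risen, 0.72, 0.727) and neutrophils (2 of 4 risen, 0.71, 0.855) were not called. The same held for podocytes (4 of 8 risen, 0.54, 0.503), collecting duct (3 of 7 risen, 1 fallen, 0.54, 0.878) and distal convoluted tubule (1 of 5 risen, 1 fallen, -0.11, 0.218), though parvalbumin, Pvalb, of the last list fell by 2.25. The test pointed lower while the median was positive for NRF2 targets (6 of 12 risen, 2 fallen, 0.58, 0.866), endothelium (2 of 11 risen, 1 fallen, 0.11, 0.503), thick ascending limb (2 of 7 risen, 2 fallen, 0.44, 0.503) and intercalated cells (3 of 6 risen, 2 over the list alone, 0.23, 0.829). Adipocyte, adrenal and erythroid lists had 1 tested gene each. These were Cfd (0.36 ± 0.95, adjusted p = 0.758), Star (-0.12 ± 0.14, 0.465) and the heme synthesis gene Alas2. Alas2 rose by 1.03 ± 0.42 (0.044) to 2.05 ± 2.4 RPKM but lost its call in 16 settings, with adjusted p up to 0.471, among them the leaving out of fl/fl DMSO number 1 (0.101), 2 (0.0759) or 3 (0.0763). None of the 13 mitochondrially encoded genes was measured.

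In total limma called 8524 of 13624 genes for 2 weeks of toxin in fl/fl cortex, 6864 higher and 1660 lower, or 80.5% higher. The median of all genes moved by 0.33, and median-of-ratios or quantile scaling took it to 0.00 and -0.07, with 50.8% and 44.8% of calls higher. Without both AA 2wk libraries numbered 3 the count was 9308, with 7315 higher and 1993 lower. Fold changes of the AA effects thus include a shift of about this size, 0.29 to 0.40 over the 4 AA effects, and a member near it is not separated from the bulk of genes.

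After the remodeling period the injury of fl/fl cortex persisted. Havcr1 stood at 329 ± 62.7 RPKM (n = 3, log2 fold change over DMSO 7.64 ± 0.86, adjusted p = 4.58e-06), Lcn2 at 302 ± 110 RPKM (6.91 ± 0.57) and Cdkn1a at 238 ± 33.2 RPKM (5.89 ± 0.18). Macrophage products were among the largest rises, with Lyz2 at 1133 ± 276 RPKM (6.96 ± 0.72) and the chemokine Ccl8 at 148 ± 16 RPKM (6.92 ± 1.06). Among the largest falls were Slco1a1 (-6.22 ± 0.31), Slc7a13 (-5.88 ± 0.49), Kap (-5.72 ± 0.55), Azgp1 (-5.45 ± 0.30) and the tyrosine breakdown enzyme Hpd (-5.20 ± 0.37). Injury genes (25 of 26 risen, median 3.23, adjusted p = 1.98e-07), p53 targets (21 of 24 risen, 1.69, 6.78e-06) and macrophage markers (13 of 13 risen, 4.13, 3.9e-05) each had an adjusted p of 0.538 with an estimated correlation. Matrix genes (26 of 29 risen, 27 over the list alone, 2.20, 0.00172) gave 0.747, inflammation (20 of 21 risen, 2.70, 2.43e-05) 0.6, cell cycle (22 of 23 risen, 1.98, 0.000534) 0.707 and T cell markers (10 of 10 risen, 3.10, 0.0124) 0.707 as the adjusted p with an estimated correlation. Col1a1 rose by 3.60 ± 0.86, Fn1 by 3.28 ± 0.53 and Mmp2, a matrix protease, by 4.38 ± 0.60. The B and plasma cell list was not called (1.47, adjusted p = 0.228), though all 4 of its genes rose.

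Metabolic genes remained low at AA 4wk in fl/fl cortex. Acadm stood at 111 ± 9.33 against 444 ± 12.5 RPKM (-1.99 ± 0.19, adjusted p = 9.44e-07), Lrp2 at -2.60 ± 0.31, and Ppara fell by 1.52 (adjusted p = 0.000367). Ppargc1a gave 0.00 ± 0.18 (0.996). Fatty acid oxidation (20 of 25 fallen, 21 over the list alone, median -0.92, adjusted p = 1.5e-14), peroxisomal lipid metabolism (14 of 18 fallen, 1 risen, -1.09, 1.22e-10), branched-chain amino acid breakdown (16 of 21 fallen, -0.99, 1.04e-12) and proximal tubule markers (19 of 26 fallen, -1.71, 1.47e-13) had an adjusted p of 0.393 with an estimated correlation. Oxidative phosphorylation (26 of 43 fallen, 22 over the list alone, -0.36, 3.42e-12), the TCA cycle (12 of 17 fallen, -0.60, 3.45e-08) and gluconeogenesis (6 of 8 fallen, 1 risen, -1.33, 0.00172) gave 0.538 with an estimated correlation, and quantile normalization ended all 3 calls (adjusted p = 0.469, 0.0956 and 0.11). PPAR-alpha targets (4 of 17 risen, 6 fallen, -0.30, 0.0333) gave 0.707, and both scalings (0.273 and 0.619) or leaving out fl/fl DMSO number 1 (0.0701) or AA 4wk number 3 (0.0655) ended that call. The sex-biased list was lower (2 of 11 risen, 6 fallen, -2.04, 0.000192, and adjusted p = 0.215 with an estimated correlation). In all 9028 genes were called, 7074 higher and 1954 lower (78.4% higher, 50.7% with median-of-ratios and 43.8% with quantile scaling), and 9749 without both AA 2wk libraries numbered 3.

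In PTKO cortex after 2 weeks of toxin, injury genes and Cdkn1a were high and tubule transporters low. Lcn2 rose from 4.29 ± 4.38 to 792 ± 284 RPKM (n = 3 each, 7.47 ± 0.57, adjusted p = 3.54e-07), Cdkn1a from 3.28 ± 0.188 to 292 ± 76.3 RPKM (6.06 ± 0.18, 1.35e-11) and Havcr1 from 8.84 ± 13.9 to 340 ± 263 RPKM (5.76 ± 0.86, 7.93e-05), with 58.7 RPKM in number 3 against 383 and 579. Lyz2 rose by 5.51 ± 0.72 and Sprr1a by 5.23 ± 0.68. Among the largest falls were Slco1a1 (-6.78), Slc7a13 (-6.46), Kap (-6.05), Inmt (-5.49) and the organic anion transporter Slc22a7 (-5.26), with SE from 0.31 to 0.55. Acadm went from 485 ± 85.3 to 113 ± 18.4 RPKM (-2.09 ± 0.19, 1.11e-06), Acsm3, an acyl-CoA synthetase, fell by 4.46 and Amacr by 2.91. Cpt1a gave -0.53 (0.0582) and Ppara -0.40 ± 0.29 (0.251). Slc34a1 fell by 1.14 and Lrp2 by 0.93 (adjusted p = 0.0098 and 0.0163). Those calls ended without PTKO AA 2wk number 1 (0.0511 and 0.0556) or 2 (0.0582 and 0.0598), and for Lrp2 also without PTKO DMSO number 2 (0.0907). Col1a1 was not called (1.27 ± 0.86, 0.211), and Fn1 rose by 2.34 ± 0.53 (0.0018). The Col1a1 value leans on PTKO AA 2wk number 3. Without that library its genotype effect at AA 2wk was 0.5, against -1.76 without number 1, and its interaction was -0.35.

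By list, fatty acid oxidation (19 of 25 fallen, 20 over the list alone, median -0.78, adjusted p = 1.43e-13), peroxisomal lipid metabolism (14 of 18 fallen, 1 risen, -0.99, 3.58e-11), branched-chain amino acid breakdown (17 of 21 fallen, 18 over the list alone, -0.92, 3.59e-13), and gluconeogenesis (6 of 8 fallen, 1 risen, -1.10, 0.00133) were lower in PTKO cortex at AA 2wk. So were the TCA cycle (13 of 17 fallen, -0.70, 4.66e-09) and proximal tubule markers (17 of 26 fallen, 1 risen, -1.10, 2.57e-11). Injury genes (25 of 26 risen, 2.94, 6.72e-08) and p53 targets (21 of 24 risen, 1 fallen, 1.79, 9.48e-08) were higher, and for these 8 lists the adjusted p was 0.411 with an estimated correlation. Oxidative phosphorylation (24 of 43 fallen, 23 over the list alone, -0.37, 7.78e-12), inflammation (21 of 21 risen, 2.16, 3.57e-06) and macrophage markers (13 of 13 risen, 3.60, 5.27e-05) gave 0.481 as that p, and cell cycle genes (22 of 23 risen, 1.79, 2.44e-05) 0.549. The sex-biased list (7 of 11 fallen, -2.46, 3.57e-06) gave 0.0563. Podocyte markers rose in 8 of 8 (1.17, 0.0204, and adjusted p = 0.531 with an estimated correlation), and immediate early genes in 11 of 12 (1.47, 0.0336, and 0.55), with Fos at 2.89. Without PTKO AA 2wk number 3 these lists had 0.0683 and 0.127, and immediate early genes had 0.053 without fl/fl DMSO number 2 and 0.0521 without PTKO DMSO number 1. T cell markers (10 of 10 risen, 2.26, 0.033, and 0.577 with an estimated correlation) had 0.0519 without fl/fl DMSO number 2 and 0.0512 without PTKO AA 2wk number 1. The matrix list was not called (15 of 29 risen, 1.21, 0.103). Its libraries varied widely, at 1.68 ± 1.26 above fl/fl DMSO, against 2.11 ± 0.77 in fl/fl cortex (mean log2 difference, SD of 3). In all 8198 genes were called, 6251 higher and 1947 lower (76.3% higher, 49.9% with median-of-ratios and 46.7% with quantile scaling), and 9534 without both libraries numbered 3. Called in both genotypes at AA 2wk were 5576 higher genes, where 3149 were expected by chance, and 1446 lower genes (237 expected), with 8 in opposite directions.

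At AA 4wk, PTKO cortex had high macrophage genes, as fl/fl cortex did, and low mitochondrial genes. From the fl/fl DMSO mean the macrophage list stood at 4.54 ± 0.22 in PTKO and 4.03 ± 0.23 in fl/fl cortex (mean log2 difference). Ccl8 rose by 7.57 ± 1.06 (adjusted p = 2.02e-05, n = 3), Lyz2 from 17.6 ± 7.9 to 1832 ± 412 RPKM (6.70 ± 0.72) and Retnla, a product of alternatively activated macrophages, by 6.66 ± 0.85 to 105 ± 17.7 RPKM. Lcn2 stood at 559 ± 110 RPKM (7.01 ± 0.57) and Havcr1 at 308 ± 32.5 RPKM (6.14 ± 0.86), and Fn1 rose from 4.83 ± 0.921 to 72.9 ± 20.2 RPKM (3.64 ± 0.53). Ndufs1 fell from 129 ± 7.38 to 51.9 ± 3.74 RPKM (-1.30 ± 0.15, 4.73e-06), Uqcrfs1 of complex III from 267 ± 6.2 to 119 ± 12.2 RPKM (-1.16 ± 0.15) and Sdha of complex II by 1.10. Acadm went from 485 ± 85.3 to 90.2 ± 14.7 RPKM (-2.41 ± 0.19, 1.68e-07) and Slc34a1 from 2504 ± 207 to 639 ± 184 RPKM (-2.01 ± 0.34). Slco1a1 (-6.61), Slc7a13 (-5.94), Kap (-5.58), the carboxylesterase Ces1g (-5.36) and Inmt (-5.25) fell strongly. Cpt1a gave -0.52 (0.0533) and Ppargc1a -0.38 ± 0.18 (0.066).

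All 43 oxidative phosphorylation genes fell in PTKO cortex at AA 4wk (median -0.74, adjusted p = 1.08e-19, and 0.394 with an estimated correlation), as did all 17 TCA cycle genes (-0.96, 2.46e-11, and 0.383). Fatty acid oxidation (22 of 25 fallen, 23 over the list alone, -1.19, 7.27e-15), peroxisomal lipid metabolism (15 of 18 fallen, 17 over the list alone, 1 risen, -1.42, 3.76e-11), branched-chain amino acid breakdown (18 of 21 fallen, -1.20, 8.49e-14) and proximal tubule markers (24 of 26 fallen, -1.87, 3.59e-15) had an adjusted p of 0.341 with an estimated correlation, and gluconeogenesis (6 of 8 fallen, 1 risen, -1.80, 0.000465) had 0.414. PPAR-alpha targets (5 of 17 risen, 6 fallen, -0.38, 0.0321, and adjusted p = 0.692 with an estimated correlation) lost their call under both scalings (0.257 and 0.585) and without PTKO AA 4wk number 2 (0.057) or 3 (0.0513). Injury (25 of 26 risen, 1 fallen, 3.15, 6.06e-06) gave 0.571 with an estimated correlation, p53 targets (21 of 24 risen, 1.82, 5.51e-05) and macrophages (13 of 13 risen, 4.45, 0.000108) 0.619, inflammation (20 of 21 risen, 2.89, 5.13e-05) 0.636, and the sex-biased list (1 of 11 risen, 6 fallen, -2.51, 6.08e-05) 0.139. Matrix (27 of 29 risen, 28 over the list alone, 2.51, 0.00179), cell cycle (23 of 23 risen, 2.05, 0.000465) and T cell markers (10 of 10 risen, 3.47, 0.00944) each gave 0.692. In all 9839 genes were called, 7488 higher and 2351 lower (76.1% higher, 50.7% with median-of-ratios and 44.5% with quantile scaling), and 10388 without both AA 2wk libraries numbered 3. Called in both genotypes at AA 4wk were 6494 higher genes (3888 expected), 1805 lower genes (337 expected) and 3 in opposite directions.

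The remodeling period itself, AA 4wk against AA 2wk, changed few genes in fl/fl cortex. Mucl1 rose from 1.11 ± 1.86 to 19.8 ± 6.22 RPKM (n = 3 each, 3.60 ± 0.47, adjusted p = 0.0066), and Clec10a, a macrophage lectin, the transferrin gene Trf and Lyl1 rose by 1.87 ± 0.34, 1.30 ± 0.21 and 1.22 ± 0.17. Ces2e, a carboxylesterase, fell from 112 ± 58.1 to 25.4 ± 4.28 RPKM (-1.96 ± 0.29, 0.0108), and Ugt1a10 (-1.81), Tmigd1 (-1.56), Apoc3 (-1.47) and the brush border protease Mep1a (-1.45) fell too. Among lists without a called member, macrophage markers were higher (median 0.94, 2 over the list alone, adjusted p = 2.65e-05, and 0.683 with an estimated correlation) and p53 targets lower (-0.37, 6 over the list alone, 1.04e-07, and 0.618). B and plasma cell markers were higher (0.66, 2 over the list alone, 0.0036, and 0.522). Limma called 17 genes, 9 higher and 8 lower, with 1672 at an unadjusted p under 0.05 and 7 by voom. A fit of only the groups compared left 0 calls, and quality weights gave 781. The call on Mucl1 ended without fl/fl AA 4wk number 1 (0.0756), and that on Ces2e without AA 4wk number 1 (0.0832) or 2 (0.0842) or AA 2wk number 1 (0.0996). The count was 1 without fl/fl AA 4wk number 1, 2 without number 2 and 7 without number 3, 5, 161 and 6 without AA 2wk number 1, 2 and 3, 90 without PTKO AA 2wk number 3, 28 without PTKO AA 4wk number 1, 10 without number 3 of that group or without fl/fl DMSO number 1 or 3 or PTKO DMSO number 2 or 3, and 43 without both AA 2wk libraries numbered 3.

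Another 10 lists were called in this comparison in fl/fl cortex, and most rest on the library numbered 3. Oxidative phosphorylation (-0.14, adjusted p = 0.000522), proximal tubule (-0.17, 0.0036), fatty acid oxidation (-0.13, 0.00433), branched-chain amino acid breakdown (-0.19, 0.00456), TCA cycle (-0.12, 0.0414) and T cell markers (0.53, 0.0414) had an adjusted p of 0.821 with an estimated correlation. Without fl/fl AA 2wk number 3 they had 0.459, 0.851, 0.765, 0.504, 0.351 and 0.499. Cell cycle genes (-0.29, 0.00583, and 0.821 with an estimated correlation) had 0.076 without number 1 and 0.445 without number 2. NRF2 targets (-0.28, 0.00635) and glucocorticoid-responsive genes (-0.24, 0.0196) gave 0.522 with an estimated correlation, and distal convoluted tubule markers (0.47, 0.0369) gave 0.653. The NRF2 call also ended without AA 2wk number 3 (0.0788), the glucocorticoid call without AA 2wk number 1 (0.0534) or AA 4wk number 2 (0.076), and the distal convoluted tubule call without AA 2wk number 1 (0.273) or 2 (0.0804) or AA 4wk number 2 (0.125) or 3 (0.051). The TCA cycle had 0.29 without AA 4wk number 1 and T cell markers 0.0651 and 0.0812 without AA 4wk number 1 and 3 and 0.0648 and 0.0581 without DMSO number 2 and 3.

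In PTKO cortex the remodeling period changed 567 genes, 354 higher and 213 lower. Mucl1 rose from 2.62 ± 2.23 to 29.2 ± 4.92 RPKM (n = 3 each, 3.21 ± 0.47, adjusted p = 0.00681), with the hormone gene Cck (3.13 ± 0.58), Lyz1 (2.74 ± 0.66), H2-M2 (2.49 ± 0.42) and Nkd2 (2.37 ± 0.49) next. Acmsd, an enzyme of tryptophan breakdown, fell from 37.9 ± 6.97 to 10.3 ± 3.48 RPKM (-1.82 ± 0.23, 0.00319), followed by Hsd3b2 (-1.52), Slc22a28 (-1.44), Acnat2 (-1.39) and Spp2 (-1.39). Csf1r, the macrophage growth factor receptor, rose from 45.7 ± 13.1 to 130 ± 21.1 RPKM (1.52 ± 0.31), while Cox7a2 of complex IV fell by 0.60. The phosphate transporter Slc17a1 fell by 1.24, and Col1a1 was not called (2.30 ± 0.86, 0.111). The Col1a1 value leans on PTKO AA 2wk number 3, without which its genotype effect at AA 2wk was 0.5. Oxidative phosphorylation was lower (median -0.37, 2 members fallen and 21 over the list alone, adjusted p = 3.62e-20), as were proximal tubule markers (-0.86, 5 fallen and 16 over the list alone, 2.02e-12), the TCA cycle (-0.30, 6.59e-08) and branched-chain amino acid breakdown (-0.29, 5 over the list alone, 1.01e-06). The matrix (1.28, 0 risen and 14 over the list alone, 2.97e-06), macrophage (0.97, 1 risen and 5 over the list alone, 0.00346) and T cell lists (1.22, 0 risen and 5 over the list alone, 0.00487) were higher. With an estimated correlation the adjusted p was 0.658 for these 7 lists and for all others called here.

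The PTKO remodeling result also leans on single libraries. Acmsd kept its call whichever library was left out, whereas Mucl1 lost it without PTKO AA 4wk number 2 (0.056) and Csf1r without that library (0.126), AA 4wk number 3 (0.0597) or AA 2wk number 3 (0.0674). Without PTKO AA 2wk number 3 the call ended for fatty acid oxidation (-0.29, adjusted p = 2.43e-06 with it and 0.281 without), peroxisomal lipid metabolism (-0.28, 0.000194 and 0.619), gluconeogenesis (-0.72, 0.0214 and 0.619), podocytes (-0.55, 0.0214 and 0.759), collecting duct (-0.40, 0.00441 and 0.619) and T cell markers (0.0583). The count of genes was 10 without PTKO AA 4wk number 2, 23 without number 3, 101 without AA 2wk number 3, 292 without number 2, 1311 without number 1, 1600 without fl/fl AA 2wk number 3, and 351 to 375 without fl/fl DMSO number 1, each of the PTKO DMSO libraries, or fl/fl AA 4wk number 2 or 3. It was 813 (457 higher and 356 lower) without both AA 2wk libraries numbered 3. Of all calls 62.4% were higher, 56.1% with median-of-ratios and 45.5% with quantile scaling, and voom called 328 genes. A replicate block within the AA 2wk groups left 107 calls, and a fit of only the groups compared left 0, against 3670 genes at an unadjusted p under 0.05 in the fit of all groups. Whether the remodeling change differs between genotypes was not tested.

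Between genotypes at AA 2wk the single called gene was Hprt, at 7.49 ± 0.593 RPKM in PTKO and 95.4 ± 9.64 in fl/fl cortex (n = 3 each, -3.50 ± 0.14, adjusted p = 1.37e-09). Genes of injury and fat oxidation gave values that were not called: Havcr1 -1.15 ± 0.86 (adjusted p = 0.893), Lcn2 1.5 ± 0.57 (0.631), Acadm -0.42 ± 0.19 (0.733), Mdm2 -0.91 ± 0.30 (0.524) and Emr1 0.78 ± 0.51 (0.86). Of these Emr1 passed only with the replicate block within the AA 2wk groups (0.0177). Single libraries moved these values by more than their SE. Havcr1 was -0.15 without PTKO number 3, Lcn2 0.8 without fl/fl number 3 and Acadm -0.65 without fl/fl number 2. Mdm2 was -0.38 without PTKO number 3 and -1.26 without PTKO number 2. Emr1 ran from 0.17 without PTKO number 2 to 1.42 without PTKO number 3. Podocyte markers were higher in 8 of 8 genes (median 0.58, adjusted p = 4.23e-10, and 0.169 with an estimated correlation), and the sex-biased list was lower (-0.28, 3 fallen over the list alone, 0.000127, and 0.15). Branched-chain amino acid breakdown (-0.35, 1.6e-06), macrophage markers (0.47, 9.02e-05), injury genes (0.16, 0.000139) and thick ascending limb markers (-0.67, 0.00809) gave 0.591 with an estimated correlation. Without fl/fl AA 2wk number 3 these 4 lists had 0.752, 0.693, 0.282 and 0.482, and the thick ascending limb also lost its call without fl/fl number 1 (0.117) or PTKO number 1 (0.137) or 2 (0.315). P53 targets (-0.32, 1.6e-06, and adjusted p = 0.55 with an estimated correlation) had 0.187 without both libraries numbered 3. Collecting duct (0.43, 3.49e-07, and 0.266 with an estimated correlation) had 0.115 without PTKO number 3.

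A further 6 lists were called at AA 2wk and are as loosely held. Fatty acid oxidation (-0.20, adjusted p = 0.00204) and inflammation (0.12, 0.00666) gave 0.888 with an estimated correlation, and without fl/fl number 3 they had 0.418 and 0.482, with medians of -0.02 and -0.21. Without PTKO number 1 or 2 fatty acid oxidation had 0.533 and 0.959, and inflammation 0.394 and 0.0743. Immediate early genes (0.43, 0.00028) gave 0.47 with an estimated correlation, NRF2 targets (-0.23, 0.0112) 0.266, and neutrophil (0.81, 0.0147) and glucocorticoid-responsive genes (0.17, 0.028) 0.31. Without fl/fl number 3 the immediate early, NRF2 and neutrophil lists had 0.102, 0.293 and 0.281, and the glucocorticoid list had 0.521 without PTKO number 3 and 0.145 without fl/fl number 2. NRF2 targets also had 0.117 without PTKO number 1 and neutrophils 0.131 without PTKO number 2. The proximal tubule list was not called, and its median of -0.01 and mean of -0.11 had the opposite sign to its test. At an unadjusted p under 0.05 there were 913 genes, and voom called 1. Residuals of libraries with the same number correlated here (0.44, 0.43 and 0.66 for numbers 1, 2 and 3). PTKO number 1 correlated more with an fl/fl library of another number, so the numbers need not mark true pairs. With replicate number as a block 3 genes were called, or 50 with the block set only within the AA 2wk groups. Leaving out fl/fl number 2 gave 110.

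After remodeling, genotypes again differed in Hprt alone among single genes (6.25 ± 1.23 in PTKO against 83.6 ± 5.98 RPKM in fl/fl cortex, n = 3 each, -3.56 ± 0.14, adjusted p = 1.1e-09), while many lists were displaced. All 43 oxidative phosphorylation genes were lower in PTKO cortex (median -0.33, adjusted p = 3.99e-28), 0 of them past the test on their own. All 17 TCA cycle genes (-0.30, 3.43e-13), 24 of 25 fatty acid oxidation genes (-0.32, 2.66e-11) and 25 of 26 proximal tubule markers (-0.45, 1.8e-11) were lower too, and so was branched-chain amino acid breakdown (-0.42, 11 members over the list alone, 9.7e-18). With an estimated correlation the adjusted p was 0.287 for each of these 5. Peroxisomal lipid metabolism (-0.38, 1.76e-07) gave 0.295 and gluconeogenesis (-0.49, 0.00025) 0.287. In mean log2 difference from fl/fl DMSO, oxidative phosphorylation stood at -0.71 ± 0.13 in PTKO and -0.37 ± 0.11 in fl/fl cortex at AA 4wk (SD of 3 libraries), and fatty acid oxidation at -1.36 ± 0.15 and -1.07 ± 0.06.

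**Figure D3:**
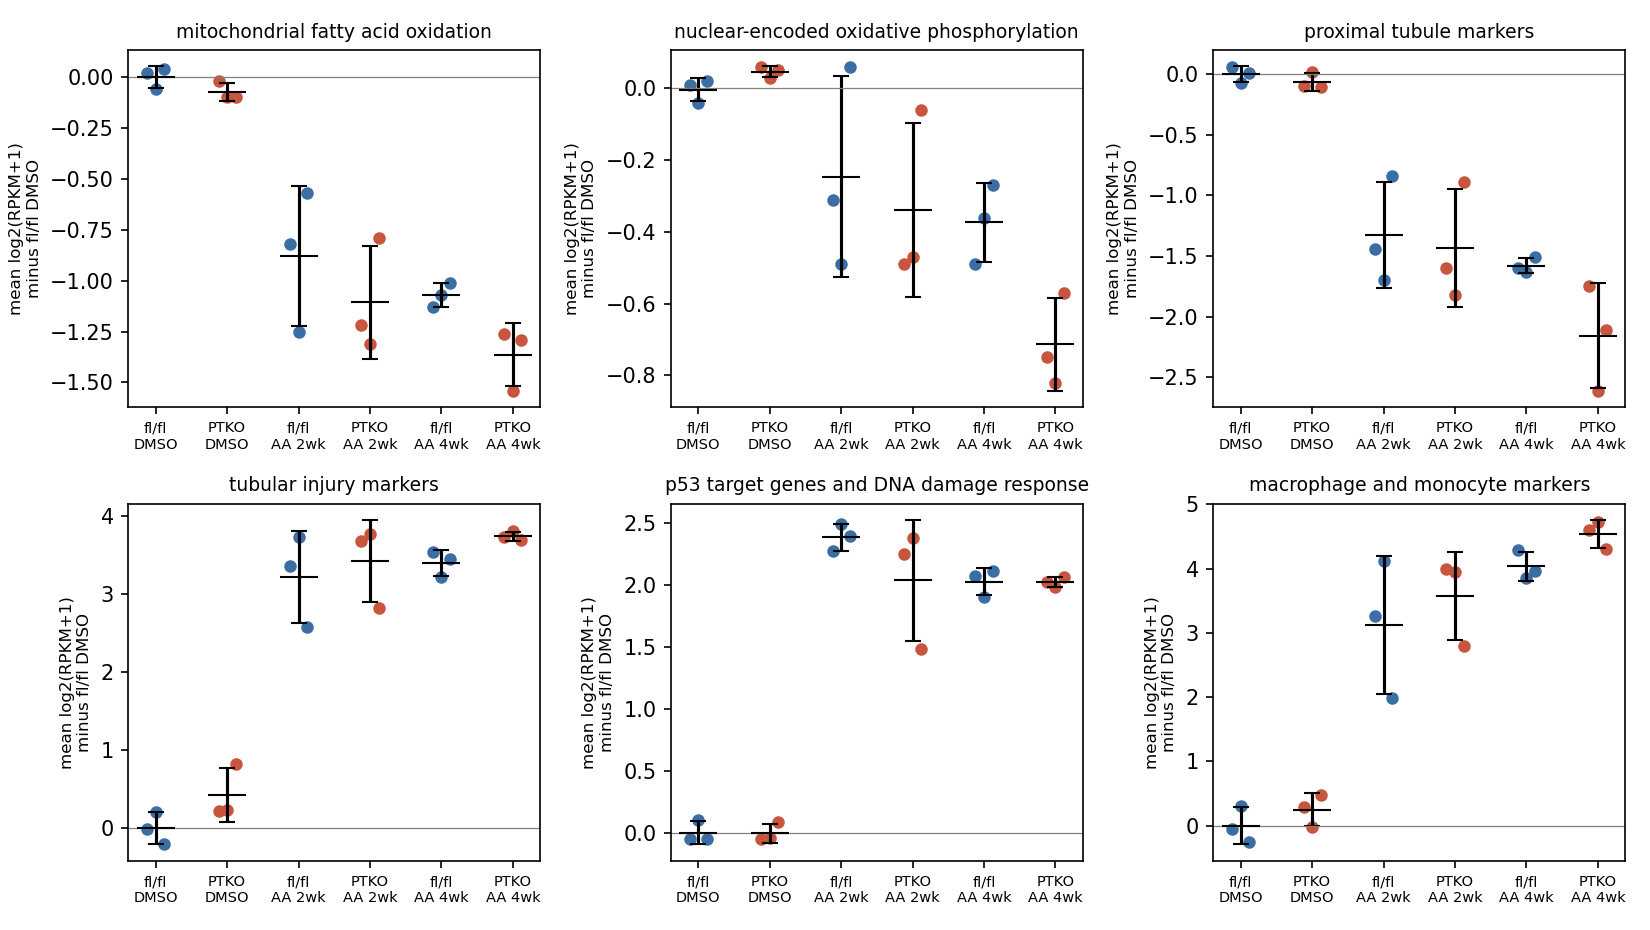
Mean log2(RPKM + 1) of 6 gene lists per library, minus the fl/fl DMSO mean (y axis, log2 units), by treatment (x axis), with fl/fl in blue, PTKO in red, points for libraries and bars for mean and SD of 3. At AA 4wk the oxidative phosphorylation list lies at -0.71 in PTKO and -0.37 in fl/fl cortex, and the macrophage list at 4.54 and 4.03.

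Matrix, cell cycle, macrophage, inflammation and T cell lists were higher in PTKO cortex at AA 4wk, while the B and plasma cell list was lower. Matrix genes were higher in 27 of 29 members (median 0.51, adjusted p = 0.000268, and 0.545 with an estimated correlation), cell cycle genes in 22 of 23 (0.39, 0.000127, and 0.517), macrophage markers in 12 of 13 (0.53, 0.00195, and 0.517) and inflammation genes in 21 of 21 (0.33, 0.00195, and 0.543). Injury genes (0.33, 0.00195) and PPAR-alpha targets (-0.21, 0.0146) gave 0.517 with an estimated correlation. Lower were intercalated cells (-0.42, 2 members over the list alone, 0.000173), distal convoluted tubule (-0.52, 0.00236) and thick ascending limb (-0.66, 0.000459), with 0.287, 0.287 and 0.326 as the adjusted p with an estimated correlation, while collecting duct (-0.11, 0.0919) and podocytes (0.08, 0.436) were not called. B and plasma cell markers were lower (-0.88, 0.00418, and 0.287), and glucocorticoid-responsive (0.18, 0.0318, and 0.287) and T cell genes (0.48, 0.0379, and 0.587) higher. The matrix, cell cycle, macrophage, inflammation, T cell, B and plasma cell and injury lists were not called in the interaction at AA 4wk. Already in DMSO, PTKO cortex stood off fl/fl cortex by 0.34 ± 0.12 for matrix, 0.18 ± 0.29 for cell cycle and 0.25 ± 0.25 for macrophage genes. Inflammation stood at 0.16 ± 0.27, T cells at 0.05 ± 0.03, injury at 0.43 ± 0.35 and B and plasma cells at -0.29 ± 0.06 (mean log2 difference).

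Single genes of these pathways were not called at AA 4wk. Slc34a1 was 639 ± 184 RPKM in PTKO and 1069 ± 104 in fl/fl cortex (-0.78 ± 0.34, adjusted p = 0.812), and passed with quality weights (0.0369) and without both AA 2wk libraries numbered 3 (0.0454). Acadm gave -0.31 ± 0.19 (0.827), Cpt1a -0.14 ± 0.23 (0.898), Lcn2 0.93 ± 0.57 (0.828), Havcr1 -0.08 ± 0.86 (0.987), Fn1 0.78 ± 0.53 (0.836) and Mki67 0.65 ± 0.38 (0.822). At an unadjusted p under 0.05 there were 823 genes, voom called 1, and without both AA 2wk libraries numbered 3 the count was 197, with 41 higher and 156 lower, and with quality weights 384, while a fit of only the AA 4wk groups called 1. Without fl/fl AA 4wk number 2 the injury, inflammation and T cell lists lost their calls (0.1, 0.1 and 0.131), and without fl/fl DMSO number 2 the T cell list did (0.0533). Others were lost by PPAR-alpha targets without fl/fl number 1 (0.0638) or PTKO number 2 (0.0895) or 3 (0.0801), T cells without PTKO number 1 (0.103) or 3 (0.0556), distal convoluted tubule without PTKO number 1 (0.0645), B and plasma cells without PTKO number 3 (0.0556), and glucocorticoid-responsive genes without fl/fl number 2 (0.162) or PTKO number 3 (0.174).

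Whether the toxin effect differs between genotypes was tested by the interaction. Hprt was the single gene with a call at both times, since it rose with the toxin in fl/fl and fell in PTKO cortex (-1.90 ± 0.20 at AA 2wk, adjusted p = 0.00108, and -1.95 ± 0.20 at AA 4wk, adjusted p = 0.000756, n = 3 per group). Tmem86a at AA 2wk was the other call (-1.42 ± 0.20, 0.0181), with 18.4 ± 2.98 RPKM in fl/fl and 12.2 ± 2.14 in PTKO cortex after toxin, against 17.0 ± 2.25 and 31.8 ± 3.16 before. That call ended without fl/fl DMSO number 1 (0.0813) or 3 (0.054), PTKO DMSO number 1 (0.0738) or 3 (0.0837) or fl/fl AA 2wk number 1 (0.0558), and with a replicate block (0.0552), over a range of 0.000278 to 0.175. Without fl/fl AA 2wk number 2 the interaction at AA 2wk had 8 calls. Injury and fat oxidation genes were not called: Havcr1 -2.57 ± 1.22 (adjusted p = 0.936) and Acadm -0.53 ± 0.26 (0.937) at AA 2wk, and Havcr1 -1.5 ± 1.22 and Acadm -0.42 ± 0.26 (both 0.934) at AA 4wk. The Havcr1 values rest largely on PTKO DMSO number 3, and without it they were -1.28 and -0.22. Unadjusted p under 0.05 was reached by 730 and 635 genes, and voom called 2 and 1.

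By list, the fall of oxidative phosphorylation at AA 4wk was larger in PTKO cortex for all 43 genes (median interaction -0.40, adjusted p = 4.72e-20, and 0.581 with an estimated correlation). The TCA cycle (-0.37, 3.26e-09) and proximal tubule markers (-0.33, 4.2e-05) followed, each with 0.581 as the adjusted p with an estimated correlation. Fatty acid oxidation (-0.27, 0.00139) gave 0.668. At AA 2wk the podocyte list stood out (0.57, 2.89e-06, and adjusted p = 0.274 with an estimated correlation). In all 10 lists were called in the interaction at AA 2wk and 12 at AA 4wk, none of them with an estimated correlation.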

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

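Of the tests in this part, those of a smaller toxin response, of scaling, of the share of proximal tubule cells and of splits sorted by replicate number were chosen only after the result was seen. The results listed first differ between genotypes in their toxin effect, as tested by the interaction (PTKO effect minus fl/fl effect, log2 scale), and list calls are given with the adjusted p of camera and the adjusted p with an estimated correlation, under which no list passed.

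For AA 2wk, Hprt (-1.90) and Tmem86a (-1.42) were the single genes. Lists with a lower toxin effect in PTKO cortex were p53 targets (median -0.35, adjusted p = 0.000479, and 0.801 with an estimated correlation), matrix (-0.69, 0.00568, and 0.962), NRF2 targets (-0.21, 0.0299, and 0.317), thick ascending limb (-0.95, 0.0213, and 0.801) and sex-biased genes (-0.46, 0.000567, and 0.128). Those with a higher effect were immediate early and heat shock genes (0.23, 0.0203, and 0.801), circadian genes (0.53, 0.000479, and 0.172), glucocorticoid-responsive genes (0.63, 0.000479, and 0.128), podocytes (0.57, 2.89e-06, and 0.274) and collecting duct (0.42, 0.000219, and 0.41). From the fl/fl DMSO mean, the circadian list stood at -0.34 ± 0.11 in PTKO DMSO (mean log2 difference). At AA 2wk it stood at -0.11 ± 0.14 in PTKO and -0.05 ± 0.15 in fl/fl cortex. Its interaction thus rests on a lower mean in PTKO DMSO, and the same DMSO libraries serve both courses. The glucocorticoid list stood at -0.33 ± 0.19 in PTKO DMSO, and at 0.88 ± 0.12 and 0.71 ± 0.10 at AA 2wk. Without PTKO AA 2wk number 3 the matrix, circadian and collecting duct lists had adjusted p of 0.632, 0.0737 and 0.134. Without fl/fl AA 2wk number 3 the NRF2, immediate early and thick ascending limb lists had 0.234, 0.248 and 0.303, and without both the p53 list had 0.205. The matrix list also had 0.146 without fl/fl DMSO number 3, 0.141 without fl/fl AA 2wk number 1 and 0.0756 without number 2. Over 100 random regroupings 24, the real one included, gave at least the real 2 genes, the highest other 742, so over all regroupings chance is not excluded for this count. The 23 others with as many each keep AA 2wk libraries of the same number on one side, which points to a structure of the samples, while of 33 that part all 3 numbers, as the real one does, 0 called a gene.

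For AA 4wk, Hprt (-1.95) was the single gene. Lists with a lower effect in PTKO cortex were oxidative phosphorylation (-0.40, 4.72e-20), the TCA cycle (-0.37, 3.26e-09), proximal tubule (-0.33, 4.2e-05), branched-chain amino acid breakdown (-0.30, 8.99e-05), peroxisomal lipid metabolism (-0.29, 0.00122), thick ascending limb (-0.93, 0.00311) and gluconeogenesis (-0.44, 0.0174), with an adjusted p of 0.581 with an estimated correlation, and fatty acid oxidation (-0.27, 0.00139) with 0.668. Those with a higher effect were circadian genes (0.39, 0.00537), the unfolded protein response (0.25, 0.0139) and the KLF family (0.19, 0.0498), with 0.581, and glucocorticoid-responsive genes (0.50, 0.00139) with 0.301. The circadian list stood at 0.05 ± 0.04 in PTKO and 0.01 ± 0.05 in fl/fl cortex at AA 4wk, so its interaction again rests on PTKO DMSO (-0.34 ± 0.11). The glucocorticoid list stood at 0.70 ± 0.20 and 0.40 ± 0.11, after -0.33 ± 0.19 in PTKO DMSO. Calls ended for the thick ascending limb without PTKO AA 4wk number 1 (0.0559), and for gluconeogenesis without number 2 (0.0693), fl/fl DMSO number 2 (0.0834) or PTKO DMSO number 2 (0.0779). The unfolded protein response had 0.135 without fl/fl DMSO number 3 and 0.0581 without fl/fl AA 4wk number 2, and the KLF family had 0.217 without the latter and failed in 15 settings. Over 100 random regroupings 2 gave at least the real 1 gene, the highest other 1, a share under 0.05.

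Both AA 2wk libraries numbered 3 lie between vehicle and the other toxin libraries. Sequencing depth is argued against, since with all libraries thinned to 10.7 M reads the nearer of them stayed at -7.0 on the first component, against 34.1 for the lowest other AA 2wk library. A smaller response to the toxin cannot be told apart from other explanations. The deviations follow the AA 4wk effect in reverse across genes (-0.71 in fl/fl and -0.63 in PTKO). The place of these libraries on the first component largely sets that sign, so it is weak evidence. P53 targets stood at 2.39 in the fl/fl library, between 2.27 and 2.49, but at 1.48 in the PTKO library, below 2.25 and 2.38. A batch shared by the libraries numbered 3 may add to this, as what is left of their deviations correlates at 0.34 across genes. That test separates weakly, with 0.32 for libraries numbered 1, 0.17 for number 2 and up to 0.24 for unlike numbers.

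Oxidative phosphorylation genes were lower in PTKO than in fl/fl cortex at AA 4wk. Scaling is argued against, since the list's median was -0.36 with median-of-ratios scaling and -0.27 with quantile normalization. A loss of proximal tubule cells and of no other cells was predicted to leave the other cell types higher, but they did not move alike. Thick ascending limb markers had a median of -0.66 (SD of members 0.35) and podocyte markers 0.08 (SD 0.2). Distal convoluted tubule had -0.52, intercalated cells -0.42, collecting duct -0.11 and endothelium -0.09. The test does not cover a lower share of several tubule segments beside more macrophages, so that stays open, as do fewer thick ascending limb cells. From fl/fl DMSO, proximal tubule markers stood at -2.16 ± 0.43 in PTKO and -1.58 ± 0.06 in fl/fl cortex, and macrophage markers at 4.54 ± 0.22 and 4.03 ± 0.23 (mean log2 difference). A stronger toxin response in PTKO cortex cannot be told apart, since the genotype effect correlates at 0.54 across genes with the AA 2wk effect in fl/fl cortex while a median of -0.26 remains once that effect is regressed out, and a direct effect of Klf15 loss is untested.

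More genes were higher than lower after 2 weeks of toxin in fl/fl cortex (80.5% of calls). Scaling cannot be told apart from a change in RNA content, because median-of-ratios scaling centers the genes and so fixes the share near the 50.8% it gave. The 50 genes with most reads in fl/fl DMSO held 17.4% of reads there and 9% at AA 2wk, and rescaling without them left 71.8% higher (69.9% to 74.1% with a library left out). They may account for part of the excess, and what remains cannot be told apart on values relative to library totals.

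With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real counts and the highest among other splits were 5 and 0 for genotype in DMSO, 1 and 1 at AA 4wk (2 splits with as many), 8524 and 3 for AA 2wk in fl/fl, 9028 and 0 for AA 4wk in fl/fl, 8198 and 0 for AA 2wk in PTKO, 9839 and 0 for AA 4wk in PTKO, and 17 and 0 and 567 and 0 for the remodeling period in fl/fl and PTKO. For genotype at AA 2wk 4 splits gave at least the real 1, the highest 2669 (fl/fl number 1 and 3 with PTKO number 3 against the rest) and the next 947 (fl/fl number 1 and 2 with PTKO number 1), which points to a structure of the samples other than genotype. Splits with more calls than the real one keep libraries of one number on the same side, whereas those that part all 3 numbers, as the real one does, called 0. With replicate number as a block 3 genes were called.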

How the results depend on the processing

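Voom on recovered reads, leaving out both AA 2wk libraries numbered 3, and the block within the AA 2wk groups are tests chosen only after the result was seen. Counts of called genes for the AA effects stayed within 1.5 times the reported ones in every setting, and at depths of 10.7 to 21.2 M reads 11323 to 13254 genes per library reach 1 RPKM, below which genes were mostly not tested. Where a library is left out of a group of 3 the fit pools the spread over all groups. The cause of the changes below was not tested, except that fewer genes or libraries enter with a stricter filter or a leave-out.

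For genotype in DMSO (5 calls) there were 1 with no filter, 1 with quantile normalization, 1 without trend or robust step, 1177 with quality weights, 2 with a replicate block, 34 without both libraries numbered 3, 14 with the AA 2wk block and 11 in a fit of the DMSO groups alone. For genotype at AA 2wk (1 call) there were 2 with a pseudocount of 0.1, 2 with no filter, 11 with weights, 3 with the replicate block and 50 with the AA 2wk block. For genotype at AA 4wk (1 call) there were 3 with no filter, 384 with weights, 2 with the replicate block, 197 without both libraries numbered 3 and 185 with the AA 2wk block. The interaction at AA 2wk (2 calls) had 158 with weights, 1 with the replicate block and 1 in a fit of its groups alone, and that at AA 4wk (1 call) 161 with weights.

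The remodeling period in fl/fl cortex (17 calls) had 10 with a pseudocount of 0.1, 7 with the stricter filter, 37 with quantile normalization, 781 with weights, 40 with the replicate block, 7 with voom, 43 without both libraries numbered 3, 91 with the AA 2wk block and 0 in a fit of its groups alone. In PTKO cortex (567 calls) it had 292, 280, 1082, 1307, 1570 and 328 in the first 6 of these settings, 107 with the AA 2wk block and 0 in a fit of its groups alone.

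With 1 library left out, counts ran from 1 to 10 for genotype in DMSO, 1 to 110 at AA 2wk and 1 to 1 at AA 4wk. They ran from 7242 to 9043 for AA 2wk and 8006 to 9540 for AA 4wk in fl/fl, 6731 to 9290 and 9011 to 10261 in PTKO, 1 to 161 and 10 to 1600 for the remodeling period in fl/fl and PTKO, and 1 to 8 and 1 to 1 for the interactions at AA 2wk and AA 4wk.

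Of single called genes, Nr3c1 in the AA 2wk effect in fl/fl reversed to -0.03 with median-of-ratios scaling, and Cd79a in the AA 4wk effect in PTKO to -0.19 with quantile normalization. Of lists, the test turned between genotypes at AA 2wk without fl/fl AA 2wk number 3 for fatty acid oxidation (median -0.02, and -0.37 without number 2) and inflammation (-0.21, and 0.47 without number 2). In the remodeling period in fl/fl cortex, medians with 1 library left out ran from -0.29 to 0.00 for fatty acid oxidation, -0.39 to 0.05 for branched-chain amino acid breakdown, -0.26 to 0.02 for oxidative phosphorylation, -0.26 to 0.03 for the TCA cycle and -0.19 to 1.01 for T cell markers. The turned ends are those without fl/fl AA 2wk number 3. Leaving out both libraries numbered 3 gave 0.00, 0.05, 0.02, 0.03 and -0.19 for these lists and 0.08 for proximal tubule, and the AA 2wk block gave 0.02 for the TCA cycle and -0.18 for T cell markers. In all, named called genes kept direction and call in 17062 values, lost the call in 779 and reversed in 2. Lists kept both in 4508 values, lost the call in 523 (153 with an estimated correlation and 93 with fry, which kept 60), and reversed in 15, while 88 values of uncalled genes passed. Other list calls ended with quantile normalization (30), quality weights (21), median-of-ratios scaling (16), the stricter filter (13) and voom (10). Not all of these lists are named here.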

Other observations

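Leaving out both AA 2wk libraries numbered 3, and the tests on single genes under it, were chosen only after the result was seen. Without these libraries the genotypes differed at AA 4wk in 197 genes, 41 higher and 156 lower in PTKO cortex. The libraries left out are not part of this comparison, so its fold changes stay as they are and only the pooled error changes, and a fit of only the AA 4wk groups called 1 gene. Among the lower genes were the organic anion transporter Slc22a8 (-1.74 ± 0.30, adjusted p = 0.0297), the inositol oxygenase Miox (-1.44 ± 0.26, 0.0297), the neutral amino acid carrier Slc6a19 (-1.15 ± 0.20, 0.0297), pyruvate carboxylase, Pcx (-1.01 ± 0.17, 0.0283), and the thiolase Acaa2 (-0.82 ± 0.13, 0.0283), but also the plasma cell gene Igj (-1.59 ± 0.28, 0.0297), Pvalb (-1.54 ± 0.28, 0.0297) and the intercalated cell gene Slc26a4 (-0.62 ± 0.12, 0.0325). Among the higher genes were the arginase Arg1 (1.75 ± 0.38, 0.0454), Gpnmb (1.13 ± 0.19, 0.0283), Ltbp2 (1.06 ± 0.17, 0.0283), Sulf1 (0.87 ± 0.14, 0.0283) and Fbln2 (0.85 ± 0.16, 0.031), the T cell genes Gzma (0.83 ± 0.18, 0.0432) and Foxp3 (0.63 ± 0.10, 0.0283), and Sprr2f (2.56 ± 0.52, 0.041). These genes were chosen after their values were seen, and the calls were not tested for enrichment of any group. In DMSO the same fit called 34 genes, among them all 5 called with every library, and Azgp1 (-1.57 ± 0.25, adjusted p = 0.029), Hpd (-1.55 ± 0.22, 0.0155), the transaminase Gpt (-0.93 ± 0.16, 0.0309) and Klf15 itself (-0.93 ± 0.15, 0.029) were lower.

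Among clock and glucocorticoid genes, Per1 stood at 13.6 ± 9.39 RPKM in fl/fl and 3.64 ± 1.02 in PTKO cortex in DMSO (n = 3 each, -1.50 ± 0.35, adjusted p = 0.392, not called). With toxin it rose in PTKO cortex by 1.70 ± 0.35 at AA 2wk (adjusted p = 0.000869) and 2.40 ± 0.35 at AA 4wk (2.77e-05), while in fl/fl cortex it gave 0.57 ± 0.35 (0.162) and 0.46 ± 0.35 (0.257). The interaction was not called at either time (adjusted p = 0.914 and 0.934). Tsc22d3, a glucocorticoid-induced leucine zipper, rose in PTKO cortex by 1.51 ± 0.30 at AA 4wk (0.000379), with 0.14 ± 0.30 in fl/fl cortex (0.701) and no called interaction (0.934).

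Hprt was lower in PTKO cortex in all 3 treatments and the nearby Gpc3 higher in DMSO, and both lie on the X chromosome. The effects averaged over treatments were -2.89 for Hprt and 0.91 for Gpc3, and Gpc3 stood at 48.5 ± 9.2 against 27.0 ± 5.2 RPKM at AA 2wk and 42.2 ± 5.84 against 24.4 ± 1.43 RPKM at AA 4wk (PTKO against fl/fl, n = 3 each, not called, adjusted p = 0.26 and 0.812). A candidate explanation is altered DNA at or near the Hprt locus in the PTKO mice, such as an inserted Cre transgene. It was tested on the other 10 tested genes within 2 Mb of Hprt, whose mean absolute genotype effect was 0.131, against a median of 0.092 in 10000 random gene sets, at percentile 85.2. Within them AW822252 gave -0.58, Gpc4 0.25 and Hs6st2 0.15, while Ccdc160 and Phf6, which lie between Gpc3 and Hprt, gave -0.05 and 0.05. At AA 4wk AW822252 gave -1.52 ± 0.38 (adjusted p = 0.812), and without both AA 2wk libraries numbered 3 it was called (-1.52 ± 0.27, 0.0297). The test leaves the explanation open, since it reached neither the bound set for it nor that set against it. It could not have counted against a change confined to Hprt and Gpc3, which it leaves out. The random sets were also not matched for expression, and the Cre line is not given in the sources used here.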
